A study of Mus musculus with 6 samples.

How the data were processed

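Total RNA was taken with Trizol and RNeasy from an Abelson pro-B line grown in RPMI with 10% serum, labelled with biotin by a core facility and measured on one-colour arrays, per the labels' protocols. Each of the 6 arrays was placed in its group by its title, giving 3 untreated and 3 tamoxifen arrays, and the replicate numbers 1 to 3 were taken from the same titles. The submitters describe the replicates as biological, without saying whether cultures of the same number shared a day or a batch. No array from tamoxifen-treated cells lacking the fusion was analysed here, so an effect of tamoxifen itself was not separated from that of the fusion. Tamoxifen acts on the fusion protein, and the level of its transcript need not move.

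The deposited matrix held log2 expression values per probe set, which were tested as deposited. Array medians lay between 7.52 and 7.61, but whether the authors normalized between arrays is not stated. That the base of the logarithm is 2 was settled from the data, since differences of group means equalled the log2 of the authors' folds to within 0.021. Partek is named in the submitters' processing notes, without a version or a role. The background correction, summarisation and normalization, the array design and the genome build are not given in the sources used here. The arrays' quartiles were not identical, so the deposited rows had not been forced to a common distribution. The authors' deposited table gave, for 251 probe sets, a gene name, a p-value and a signed linear fold, where a fall by n-fold is written as -n, which serves as a score with no values between -1 and 1. Its test is not stated in the sources used here. Its p-values correlated at 0.9992 on the log10 scale with those of an unmoderated per-probe-set test with equal variances, and at 0.743 with a paired one. Such a test without adjustment, at p under 0.05 and a fold over 1.5, would select 372 probe sets, of which 247 were in the table and 124 of the other 125 lay in the block numbered below the table's lowest probe set. After Benjamini-Hochberg adjustment that test gave 40 probe sets past 0.05.

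Gene symbols were brought up to date through a RefSeq gene table of the assembly GRCm38.p6. It was used for names and for which genes neighbour each other, by the order of their start coordinates on each chromosome. Its coordinates had no other use. Of the 251 rows, 200 were matched by accession, 15 by gene number, 9 by symbol and 8 by synonym, 8 kept their deposited name and 11 had none, which gave 225 different symbols. For a gene with several probe sets, the one with the highest mean over all 6 arrays stood for the gene.

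Differences were tested with limma 3.58.1 in R 4.3.3, with lmFit and eBayes on the log2 values as deposited, with 2 groups and no covariate, and with Benjamini-Hochberg adjustment over all 35557 probe sets at a threshold of 0.05. The prior degrees of freedom were 2.49, beside 4 residual degrees of freedom. p-values measure the spread between these arrays. The procedure was tested on simulated data built on these 35557 probe sets, with 200 changed probe sets in each of 10 runs. It recovered 50.3% of 1.5-fold, 79.6% of 2-fold and 95.6% of 4-fold changes, and 5.83% of its calls were false. The simulated values were drawn independently for each array, without the structure across arrays that is described below. These rates therefore need not hold for the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

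The test, its alternatives, the rule for named genes and 30 gene lists were set before the data were examined. The rule named Gfi1b, Rag1, Rag2, Foxo1, Gfi1, Ikzf1, Ebf1, Pax5 and Tcf3 whatever their values. It added, in each direction, the 10 genes with the largest change among those past the threshold with groups that did not overlap, passing over predicted and unnamed genes, and up to 4 members of each list. Sesn3, a FoxO target, falls outside it and was named after its values were seen. A list member that the rule chose is not reported here by name or value, although counts of list members and the tests on them include it. Of the first 9 genes, Rag1 and Rag2 had a name in the table, and the other 7 were not analysed here.

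The plan was departed from in 3 ways once the files had been seen. The plan was to test 1 probe set per gene, but names exist here for the table's rows alone, so all probe sets were tested. The planned camera and fry tests of the gene lists were not run, since the members that can be named were selected by the authors for their change. In their place the members present were counted, and for a list with at least 5 of them the direction was set against the other named genes with Fisher's exact test, two-sided, a test chosen after the files had been seen. The FoxO targets were the 1 such list. The alternatives were the replicate number as a block, leaving out dim probe sets, quantile normalization, median centring, an intensity trend with robust variance, array weights, the mean of a gene's probe sets, a threshold of 0.1, limma's treat against a fold of 1.2 and leaving out each array in turn. A further 3 were added after seeing the data, namely leaving out the low-numbered block, leaving out both arrays of replicate 2, and a covariate from the residuals.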

Results

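The series measured transcript levels in a mouse pro-B cell line transformed by Abelson murine leukaemia virus, a retrovirus whose v-Abl kinase keeps B lineage precursors dividing in culture. The line carried, from a retrovirus, Gfi1b joined to the hormone-binding domain of the oestrogen receptor. Gfi1b is a zinc finger transcriptional repressor of blood cell precursors, and tamoxifen switches on proteins joined to this domain. Total RNA from 3 untreated cultures and 3 cultures kept in tamoxifen for 12 h, described by the submitters as biological replicates, was measured on 6 one-colour arrays. The deposited values were log2 expression for 35557 probe sets, with array medians between 7.52 and 7.61. The number of arrays limits the precision of every value given here. Gene names were at hand for the 251 probe sets in the authors' deposited table of changed genes, and all other probe sets were tested without a name. Gfi1b itself and Foxo1 were not analysed here, because no row of that table names them.

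The comparison of tamoxifen with untreated cells asks which transcripts change once the Gfi1b fusion is active. Both recombination activating genes, whose products together cut DNA at antigen receptor loci, fell. Rag1, on chromosome 2 in band E2 (probe set 10485372), went from 11.34 ± 0.13 in untreated cells to 9.06 ± 0.095 with tamoxifen (log2, mean ± SD, n = 3 each). That was a log2 fold change of -2.28 with a standard error of 0.089 and an adjusted p of 0.00082 (limma, Benjamini-Hochberg). Rag2, its neighbour in the same band (probe set 10474105), went from 8.72 ± 0.19 to 6.89 ± 0.088 (n = 3 each), a log2 fold change of -1.83 ± 0.11 (SE; limma adjusted p = 0.0031). A dimmer Rag2 probe set had a log2 fold change of -0.72 and did not pass (limma adjusted p = 0.060). The most reduced named transcript was Ctss, the lysosomal protease cathepsin S that trims the invariant chain of MHC class II, which fell 7.05-fold from 11.77 ± 0.045 to 8.95 ± 0.021 (SD, n = 3 each; limma adjusted p = 3.7e-05). Gimap4, a GTPase of lymphocytes, fell 5.40-fold, with a log2 fold change of -2.43 ± 0.066 (SE).

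Several cell surface proteins were among the 10 largest named falls. The tetraspanin Cd53 fell 4.79-fold, the Fc receptor-like protein Fcrl1 of B cells 4.16-fold, the scavenger receptor Cd36 4.04-fold and the TNF receptor family member Tnfrsf19 3.42-fold. With tamoxifen Cd36 averaged 6.01, below the lower quartile of every array, and without a measure of background its fold is uncertain. The secreted protein Crisp1 fell 4.51-fold, and Rgs18, which speeds the shut-off of G proteins, fell 3.71-fold. The largest adjusted p among these 6 genes was 0.0066, for Cd53 (limma). The largest named rise was that of Ptgs1, the prostaglandin synthase also called COX-1, from 7.83 ± 0.14 to 9.87 ± 0.13 (SD, n = 3 each), a log2 fold change of 2.04 ± 0.099 (SE; limma adjusted p = 0.0013). Pgf, a growth factor of the VEGF family, rose 3.30-fold, and the antiviral membrane protein Ifitm3 rose 2.94-fold (limma adjusted p = 0.017 and 0.030). Of the 6 fits that each left out 1 array, Pgf passed in 2 and Ifitm3 in 0. H2-DMb2, a chain of the protein that loads peptides onto MHC class II, rose 2.68-fold, the collagenase Mmp13 2.57-fold, and the interleukin 1 decoy receptor Il1r2 2.55-fold. Lyz2, a lysozyme of myeloid cells, rose 2.39-fold, and Bhlha15, a transcription factor of secretory cells also called Mist1, rose 2.35-fold with a standard error of 0.059 on the log2 scale. The kinase Camkk1 rose 2.22-fold and the membrane protein Tmem86a 2.14-fold. From H2-DMb2 to Tmem86a, the largest adjusted p was 0.014, for Camkk1 (limma).

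**Figure D1:**
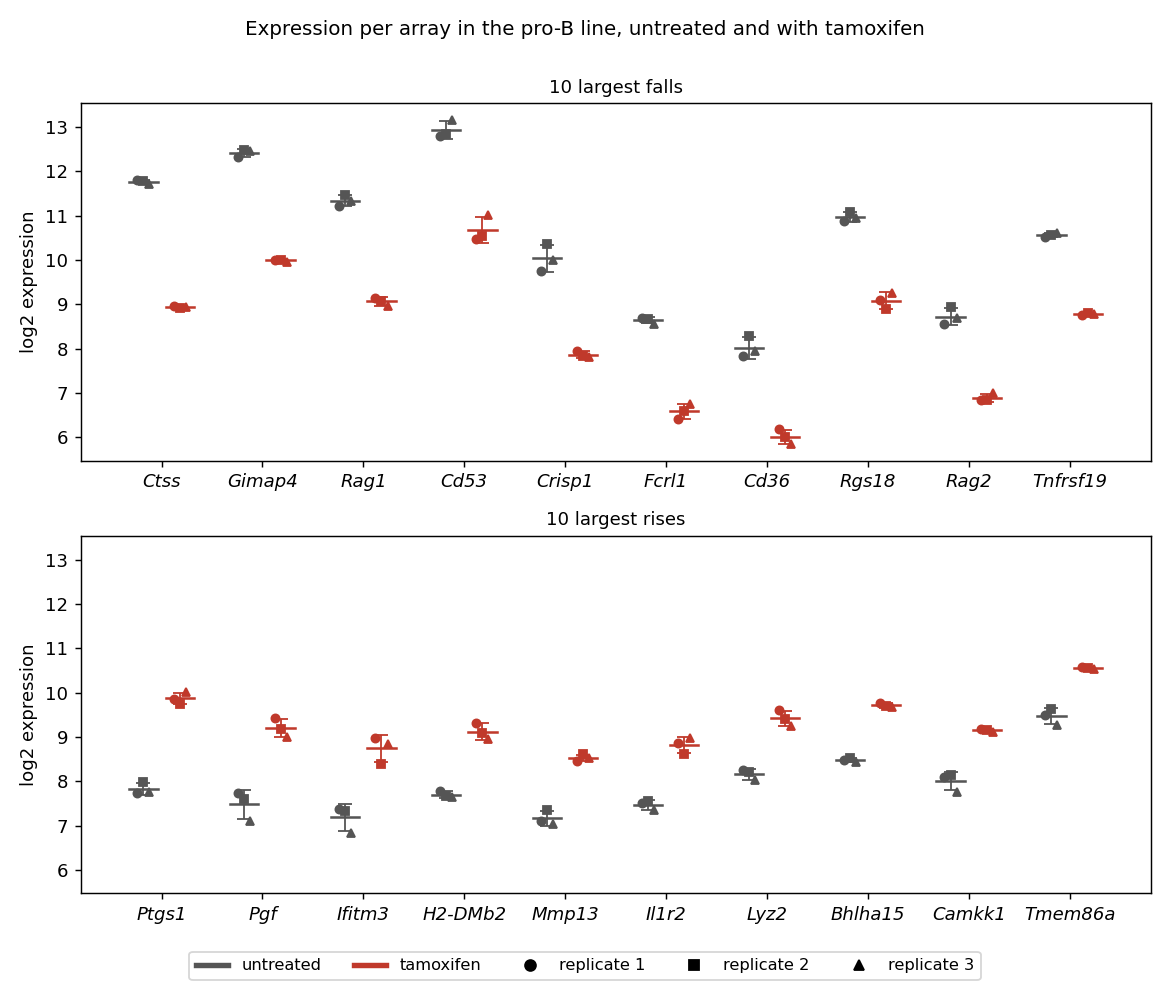
Log2 expression (vertical axes) of the 10 named genes with the largest falls and the 10 with the largest rises, with untreated arrays in grey and tamoxifen arrays in red, a symbol per replicate number, and bars for the mean ± SD of 3 arrays. The naming rule admitted only genes whose groups do not overlap, and among these 20 Ctss shows the widest gap, 11.77 against 8.95.

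In all, 316 of 35557 probe sets passed an adjusted p of 0.05, 154 of them higher and 162 lower with tamoxifen. A change of 2-fold or more was called for 22 higher and 36 lower, and of 4-fold or more for 1 higher and 8 lower. Of the 225 genes with a name, 66 rose and 102 fell past the threshold. Without an adjustment 4529 probe sets had p under 0.05, where chance gives 1778 if the arrays hold no other structure. A split of the arrays that crosses the labels, untreated 1 and 3 with tamoxifen 2 against the rest, gave 9593. That split keeps replicates 1 and 3 apart by treatment, so treatment can add to its count. The remaining splits into 3 and 3 gave between 679 and 1484. The excess therefore cannot be credited to treatment alone. In the 316 called probe sets the 3 tamoxifen values all lay on one side of the 3 untreated values, which held for 18.3% of all probe sets where chance gives 10%. The 35557 probe sets include a block of 6667 numbered below the lowest number in the authors' deposited table. What the block measures is not given in the sources used here. Without it, in a fit added after seeing the data, 332 higher and 308 lower probe sets were called. The counts with all probe sets also leaned on single arrays. Leaving out any array but untreated replicate 2 left between 38 and 59 called probe sets, and leaving out untreated replicate 2 gave 414. At 2-fold or more the balance then turned, to 88 higher and 33 lower, and to 116 higher and 33 lower without both arrays of replicate 2, a fit added after seeing the data. Of the 247 rises of any size in that last fit, 125 lay in the block and 148 fell between the arrays of replicate 2. The turned balance therefore cannot be told apart from the structure of the arrays that crosses the labels. Of the 37 genes chosen by the naming rule that passed with all arrays, 15 passed in all 6 fits that each left out 1 array. These were the 10 largest falls together with Ptgs1, H2-DMb2, Mmp13, Bhlha15 and Tcf7.

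Gene lists fixed before the data were examined were set against the named genes. Because the authors had chosen the table's genes for their change on these same arrays, a count of members there is not independent evidence about a list. Of 36 FoxO target genes, the table held 5, and all 5 fell past the threshold. Besides Rag1 and Rag2 these included Trp53inp1, an autophagy and stress protein (log2 fold change -0.79 ± 0.074, SE), and the sestrin Sesn3 (-0.83 ± 0.12), with limma adjusted p of 0.014 and 0.048. Set against the other named genes, of which 96 were higher and 124 lower, their direction did not pass (Fisher's exact test, two-sided, p = 0.0732), and with 5 members that is the p of the most falls there can be. No count adjusted over the list alone is given, because members outside the table have no name here. Rag1 and Rag2 were also the 2 members present of the 19 genes of V(D)J recombination and end joining.

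B lineage genes moved in both directions. Of 28 early B lineage transcription factors 3 were in the table, and of these the Ikaros family member Ikzf3 (log2 fold change 0.63) and the Ets factor Spib (0.92) rose, with limma adjusted p of 0.025 and 0.031. Lmo2 had a log2 fold change of 0.59 and did not pass (limma adjusted p = 0.065). Among pre-B receptor and B cell signalling genes, the kinase Blk fell by 0.81 and the receptor chain Cd79b rose by 0.65 on the log2 scale (limma adjusted p = 0.0096 and 0.021). Among the mature B cell genes present, Fcrl1 fell, the chemokine receptor Cxcr5 rose 2.03-fold, and Cd55 had a log2 fold change of 0.68 with a limma adjusted p of 0.10. Both plasma cell genes present rose, namely Prdm1, the repressor Blimp-1 (log2 fold change 0.89 ± 0.098, SE), and Xbp1, a factor of the secretory pathway (0.61 ± 0.073), with limma adjusted p of 0.020 and 0.025. Xbp1 was also the member present of the lists for the oestrogen response and the unfolded protein response.

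Few members of the fixed lists for other blood cells were in the table, and markers outside those lists were not counted. The lysozymes Lyz1 and Lyz2, the 2 of 30 myeloid genes present, both rose, Lyz1 by 0.64 on the log2 scale (limma adjusted p = 0.0081). The 2 lie side by side and are similar in sequence, so that their probe sets can read each other's transcripts. Of the 2 T and NK cell genes present, the transcription factor Tcf7 rose by 0.85 on the log2 scale (limma adjusted p = 0.0060), while the kinase Zap70 had a log2 fold change of 0.63 with a limma adjusted p of 0.078. The 2 stem and progenitor genes present, Lmo2 and the HLH inhibitor Id2 (log2 fold change 0.63, limma adjusted p = 0.14), did not pass.

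Signalling genes in the table also split by direction. The kinase Sgk1, the member present of the PI3K and Akt list, fell by 0.65 on the log2 scale (limma adjusted p = 0.017). Of the immediate early and NF-kB genes, Rel and the phosphatase Dusp4 fell, each by 0.70 on the log2 scale (limma adjusted p = 0.014 and 0.026), and Jun had a log2 fold change of -0.82 with a limma adjusted p of 0.12. The cytokine signalling inhibitor Cish rose 2.10-fold (limma adjusted p = 0.025). Of the 2 members present of the interferon response list, the RNA sensor Dhx58 rose by 0.70 on the log2 scale (limma adjusted p = 0.042). The other, Ifih1, had a log2 fold change of 0.63 with a limma adjusted p of 0.054. Interferon-related genes outside the list were not counted, so no shared direction of such genes is shown. The prolyl hydroxylase P4ha1, from the glycolysis and hypoxia list, fell by 0.58 on the log2 scale (limma adjusted p = 0.029). The cholesterol exporter Abca1, a liver X receptor target, had a log2 fold change of -0.80 with a limma adjusted p of 0.10. Trp53inp1 was the member present of the p53 target list, and Cd53 was among those of adhesion and migration. Across all 30 lists the table held 30 different genes, of which 11 rose and 12 fell past the threshold. It held no member of the lists for Gfi1b and its LSD1 and CoREST cofactors, erythroid and megakaryocyte genes, stromal cells, DNA replication, mitosis, D cyclins and Cdk inhibitors, Myc and ribosome biogenesis, Bcl2 family apoptosis, cholesterol synthesis, replication-dependent histones, or housekeeping genes. Absence from a table of selected genes does not show that these genes kept their level.

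**Figure D2:**
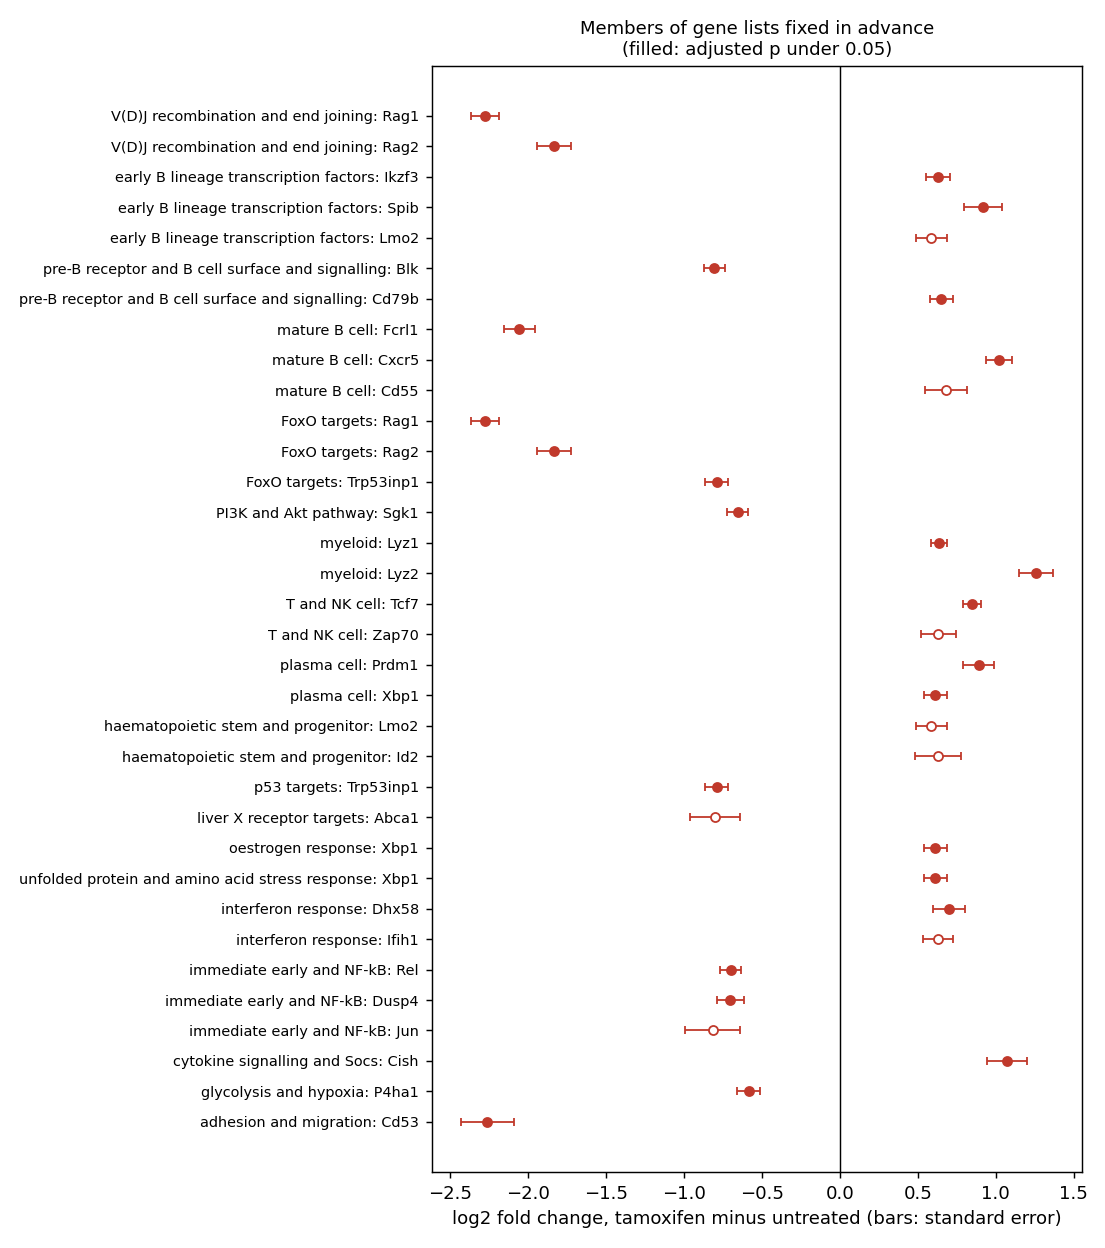
Log2 fold change, tamoxifen minus untreated (horizontal axis), of up to 4 members per fixed gene list, from those with the smallest p, with bars for the standard error (3 arrays per group) and filled points for an adjusted p under 0.05. The FoxO targets shown all lie below 0, down to Rag1 at -2.28, and both plasma cell genes lie above it.

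The authors' deposited table gave 102 probe sets as higher and 149 as lower with tamoxifen, with folds of 1.503 or more and p of 0.0451 or less. All 251 had the same sign in the values tested here, and the largest difference in log2 fold change was 0.021. Of the 251, 182 passed the adjusted p of 0.05. Ctss, Gimap4 and Rag1, the 3 largest named falls, stood in the authors' deposited table at signed folds of -7.09, -5.41 and -4.86. A further 134 probe sets passed here without being in the table, 86 higher and 48 lower, and they remain without a name. Of the 58 called changes of 2-fold or more, 54 were in the table.

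The arrays also differed in a way that treatment did not explain. Component 1 of the 6 arrays held 46% of the variance and placed untreated replicates 1 and 3 at 30.6 and 26.5 and tamoxifen replicates 1 and 3 at -26.6 and -23.4. Replicate 2 lay between them and in the opposite order, with untreated at -9.74 and tamoxifen at 2.67. A block of 6667 probe sets, those numbered below the lowest number in the authors' deposited table, showed the same crossing. The block's median was 7.26 and 7.27 in untreated replicates 1 and 3 against 7.53 and 7.48 in tamoxifen replicates 1 and 3. In replicate 2 it was 7.50 untreated and 7.31 with tamoxifen. The block held 25 of the called rises and 4 of the called falls, none of them named.

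**Figure D3:**
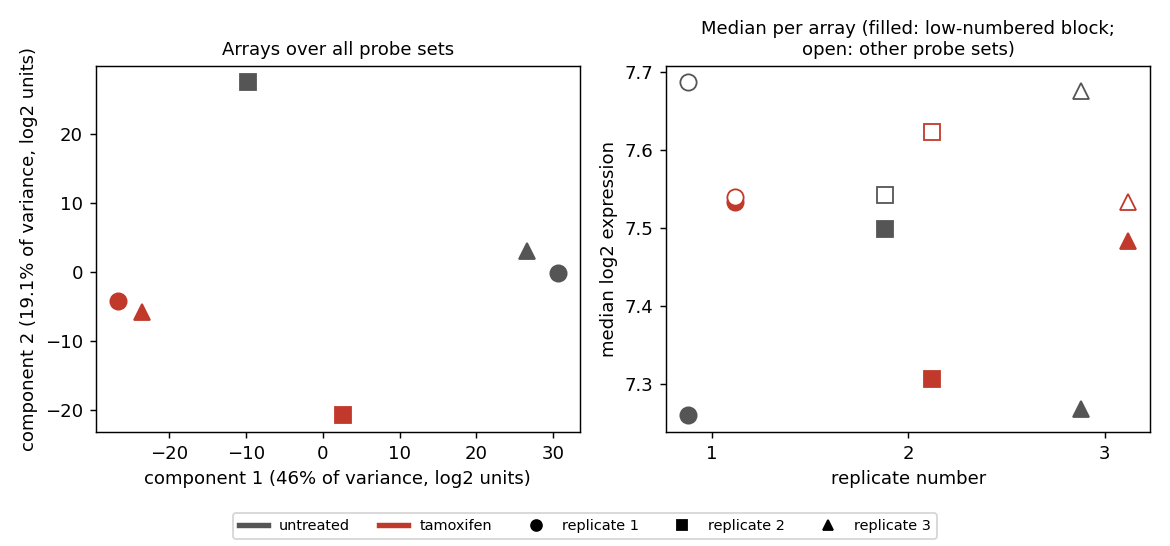
Left, the 6 arrays on components 1 and 2 over all probe sets (log2 units, 46% and 19.1% of the variance); right, each array's median log2 expression in the low-numbered block (filled) and in the other probe sets (open) by replicate number, with untreated in grey and tamoxifen in red. Replicate 2 departs from replicates 1 and 3 in both panels, with a block median of 7.50 untreated and 7.31 with tamoxifen.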

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

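The 3 alternatives marked as added were chosen after seeing the data. The log2 fold change of Rag1 lay between -2.34 and -2.21 and that of Rag2 between -1.92 and -1.28, past the threshold in every alternative run for them (limma adjusted p at most 0.0305 and 0.0403); the smallest Rag2 change was the mean of its probe sets. None of the other 42 named genes reversed in any alternative, which shows little, since they were chosen for their change on these arrays and several alternatives leave every fold as it is, that of Rag1 included. Of the 44 named genes, Rag1 and Rag2 included, 37 passed with all arrays. Of these 37, 23 lost their call with the replicate block and between 4 and 20 when 1 array was left out.

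Counts of called probe sets moved far more, and except where the construction shows it (fewer arrays or probe sets, another threshold) the cause was not tested. Against 154 higher and 162 lower, there were 515 and 342 without dim probe sets, 410 and 311 with an intensity trend, 814 and 376 with array weights, 364 and 294 at an adjusted p under 0.1, and 21 and 34 with treat. Quantile normalization gave 212 and 309, and median centring 130 and 104. The added alternatives gave 332 and 308 without the low-numbered block, 247 and 85 without both arrays of replicate 2, and 588 and 374 with the residual covariate. With 1 array left out, higher calls ranged from 9 to 278 and lower from 28 to 136. Changes of 2-fold or more, 22 higher and 36 lower, gave 92 higher with array weights and 116 higher without both arrays of replicate 2. They ranged from 5 to 88 higher and from 23 to 33 lower with 1 array left out. The called members of fixed lists, 11 higher and 12 lower, ranged in those fits from 2 to 12 and from 4 to 9. The 182 called rows of the authors' deposited table ranged from 38 to 168. Without both arrays of replicate 2 these rows were 119. Among the fits with 1 array left out, the one without untreated replicate 2 had the most higher calls.

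The values gave no sign that replicate numbers pair the arrays, but they cannot exclude it. The first residual component had opposite signs in the arrays of each number and could mask a smaller shared effect. Deviations from the group means correlated at -0.229, -0.45 and -0.0957 between arrays of the same number, and no array deviated most like the one of its own number. With the replicate block 6 higher and 16 lower probe sets were called, all of them 2-fold or more, and 1 higher and 4 lower list members and 22 rows of the authors' deposited table. All 22 were among the 316. Camera and fry were not run, and signal over background was not among the values used here, so what dimness limits is not known beyond the alternative without dim probe sets.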

Other observations

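The groups and tests in this part were chosen after the values were seen, except the tests of array intensities, of the block, of brightness and of gene positions, whose outcomes were stated before those results were seen. By symbol or description, 15 rows of the table are of immunoglobulin heavy or kappa chains, and all 15 were lower with tamoxifen, by 1.53-fold to 2.03-fold, 11 of them past the limma threshold. The row for the heavy chain complex, Igh, went from 11.63 to 10.75 (log2 fold change -0.88 ± 0.066, SE, n = 3 per group, limma adjusted p = 0.0066). Variable segments are similar in sequence and 4 of the rows name the same segment, so the rows are not independent and no p is given for their shared direction.

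Receptors coupled to G proteins moved both ways, with 6 falling and 2 rising past the threshold. P2ry10, a receptor for lysophospholipids on lymphocytes, fell 3.35-fold and its neighbour Gpr174 fell 2.27-fold (limma adjusted p = 0.00085 and 0.025). Lpar6, a receptor for lysophosphatidic acid, fell 2.59-fold, while Cxcr5 and the melanocortin receptor Mc1r rose 2.03-fold and 2.04-fold. The direction of this group gave a Fisher's exact p of 0.523, or 0.697 adjusted over the 4 groups tried. All 3 RGS genes in the table, Rgs18, Rgs16 and Rgs8, fell (Fisher's exact p = 0.263, adjusted 0.526). Of 10 exchange factors and GTPase-activating proteins picked from the table, 5 were higher and 5 lower (Fisher's exact p = 0.747).

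Of the 10 splits of the 6 arrays into 3 and 3, the labelled 1 called 316 probe sets and the highest other 15, and with 10 splits a share under 0.05 cannot be reached. At an unadjusted p under 0.05, untreated 1 and 3 with tamoxifen 2 against the rest gave 9593 probe sets, 2.12 times the 4529 of the labelled split, which points to a structure of the arrays that crosses the labels. Different intensity distributions and the low-numbered block are argued against as its whole cause, since the ratio was 1.59 after quantile normalization and 2.02 without the block. A swap of labels in replicate 2 was left undecided by all 332 probe sets called from replicates 1 and 3 alone, of which a share of 0.521 kept its direction in replicate 2. A narrower test was chosen after that outcome. Of the probe sets that fell, 0.871 (74 of 85, exact 95% binomial limits 0.78 and 0.934) also fell in replicate 2. These limits are too narrow because probe sets are not independent. Among falls of 2-fold or more, 31 of 33 also fell, by a median log2 change of -1.8 in replicate 2. The rises went the other way, as 99 of 247 also rose in replicate 2. The falls argue against a swap for the probe sets they cover, and both directions together leave it undecided. A technical difference shared by untreated 1 and 3 and tamoxifen 2 may remain, as 148 of the 247 rises turned in replicate 2, 94 of them in the block. The labels name no batch to test it. The titles of untreated 1 and tamoxifen 2 (the pair whose deviations from the group means correlated most, at 0.345) share a letter A of unstated meaning that untreated 3 lacks. No biological explanation was tested.

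With all arrays, the mean size of called changes on the log2 scale was 0.866 for 162 falls and 0.693 for 154 rises, a difference of 0.172 (permutation test of direction, two-sided, 100000 permutations, p = 4e-05, too small because probe sets are not independent). The compression of dim probe sets and the low-numbered block are argued against as its cause, since the difference was 0.175 within tertiles of brightness (permutation p = 4e-05) and 0.178 outside the block (permutation p = 0.00015). The arrays of replicate 2, untreated replicate 2 above all, are a candidate cause. The difference was 0.0494 without both arrays (permutation p = 0.27) and 0.0595 without untreated replicate 2, but 0.494 without tamoxifen replicate 2. Without any other array it was 0.317 to 0.554. The fits are not alike, since without both arrays 332 probe sets were called, without untreated replicate 2 414, and without any other array between 38 and 59. The arrays left without replicate 2 also lie apart by treatment on component 1, so rises of that structure may enter the calls. At 2-fold or more, the 36 falls and 22 rises became 33 falls and 116 rises without both arrays and 33 falls and 88 rises without untreated replicate 2. The difference was also smaller with array weights, at 0.0221, and after quantile normalization, at 0.0683, so no biological explanation is offered for it.

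Of 209 genes of the authors' deposited table placed on the reference, 19 pairs lay within 3 positions, against a median of 6 and a highest of 17 in 10000 random sets of protein-coding genes (permutation p = 1e-04, the smallest they can give). Pairs whose symbols differ in their first 3 letters, which leaves out most pairs of related genes that may share probes, numbered 13, where the middle 95% of random sets reached up to 10 (permutation p = 0.0026). Related genes still add to these 13, as Lyz1 and Lyz2 each pair with Cpm, Rag1 and Rag2 with Lrrc4c, and P2ry10 and P2ry10b with Gpr174. The effect of related genes is therefore not fully removed. Of the 19 pairs 15 had the same direction, a count not set against chance, among them Rag1 and Rag2, Camkk1 and P2rx1, and P2ry10 and Gpr174, while Lyz1 rose and Cpm fell. The random sets were drawn from all protein-coding genes, not from those measured or expressed in pro-B cells, and a clustering of expressed genes along chromosomes was not tested and stays open.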
